A study of Mus musculus with 11 samples.

How the data were processed

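The data were 11 single-colour Illumina mouse expression arrays of a mouse embryonic fibroblast line that lacks p53 and TSC2. Groups were taken from the submitters' labels: luciferase siRNA with ethanol (2 arrays), luciferase siRNA with rapamycin (3), Crebl2 siRNA with ethanol (3) and Crebl2 siRNA with rapamycin (3). The design text of the series calls the target Creb2 and gives 2.5 days of siRNA, while the labels name Crebl2 and 3 days. Crebl2 was used here as the labels give it. Rapamycin was used at 20 nM for 12 h. The labels do not say what the replicates are, so p-values measure only the spread between these samples.

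Per the labels, total RNA was isolated with TRIZOL and amplified with a biotin-labelling kit, with Cy3-streptavidin detection. Per the file headers, the deposited non-normalized table holds a mean bead intensity on a linear scale for each probe and array, with a detection p-value that the signal is above background. The authors' normalized table holds intensity values on a linear scale after a normalization between arrays, with its own detection p-values. The deposited series matrix holds the same intensity values, with 0 values different. Scanner software, background step and the method of the authors' normalization are not given in the sources used here. Column medians of the authors' normalized values lay between 110.5 and 112.4.

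The 46237 probe identifiers of the non-normalized table did not belong to the values on their lines. Across probes, the log2 values of this table and of the normalized table correlated between -0.00964 and -0.00628 on an array when joined by identifier. Each line was therefore matched to the line of the normalized table with the nearest ranks on all 11 arrays. All 46237 lines matched 1 line that matched back, each to a different line. The distance to the match was at most 19.2% of that to the next line, and 32 lines kept their identifier. After the match the tables correlated between 0.999653 and 0.999996 on each array. On simulated data 100% of lines were put back in place.

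As a check of which table names its probes correctly, 493 probes of housekeeping genes and 1675 probes of olfactory and similar receptor genes were counted as detected at p under 0.01 on at least 8 arrays. With the identifiers of the non-normalized table, 34.3% of the housekeeping and 38.8% of the receptor probes were detected. With those of the normalized table the shares were 79.5% and 1.97%, and after the match they were 79.5% and 1.91%. The levels of 2 probes of 1 symbol, over 8275 symbols, correlated with r = -0.0017 in the non-normalized table and 0.477 in the normalized table. The identifiers of the normalized table were used throughout. This mismatch was found after a first run on the listed identifiers, whose results were dropped. The authors' normalized values serve as an alternative whose intensities do not rest on the match. Its filter does, since it used the matched detection p-values of the non-normalized table.

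From the non-normalized intensities, background was corrected and arrays were quantile normalized with neqc of limma 3.58.1 (offset 16, negative-control parameters inferred from the detection p-values), under R 4.3.3 with the data.table package, version 1.17.8. Probes detected at p under 0.05 on at least 2 arrays were kept, 28771 of 46237. Probe names came from the platform annotation supplied with the data: 35784 probes had 1 gene symbol, 0 had several and 10453 had none. By Entrez identifier 28620 were matched to a current gene, with 0 symbols changed. Of the kept probes 23572 had a symbol, and the probe with the highest mean over the 11 arrays stood for its gene, which gave 15835 genes. Where probes of a named gene disagreed the text says so.

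All 4 groups entered 1 limma fit (lmFit and eBayes, 7 residual and 3.21 prior degrees of freedom) with no block. The comparisons were the knockdown in ethanol and in rapamycin, rapamycin with each siRNA, the interaction, and the mean knockdown and mean rapamycin effects. Adjustment was by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. Changes are differences of mean log2 levels, with the standard error of the fit. A gene not above background on any array of a group has only a bound there. Its floor was the mean, over the arrays of that group, of the higher of the lowest detected signal of the array and the probe's own signal, and the fold is given as "at least". Lists of genes for growth, metabolism, stress responses, fibroblasts and other cell types were tested with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the 27 lists that had at least 5 genes tested. Camera with an estimated correlation and fry were alternatives. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. The marker lists of muscle and of adipocytes had too few genes tested.

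The groups, tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule takes Crebl2, Crebrf, Tsc2 and the p53 gene in every group whatever their result. In each comparison it takes, among genes past the threshold whose arrays do not overlap between the compared groups, the 8 largest increases and 8 largest decreases, with no condition on overlap for the interaction and the mean effects. For each list that passed it takes the 3 members with the smallest p called in the direction of the list, and for other lists described up to 2 members with the smallest p. Only probes with 1 symbol count, and gene models named only by a clone or locus identifier may be left out. The text names part of the genes this rule gives, and that part, like the 8 genes plotted per array, was picked after their values were seen. The p53 gene was not analysed here. Chosen after seeing the data were the match of identifiers, the 4 arrays that stood apart as a block or left out, and the count of genes with at least 2 kept probes that agree.

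In a test on simulated data with the spread of these arrays, 200 of 15835 genes were changed. For the knockdown in ethanol, the knockdown in rapamycin, rapamycin with luciferase siRNA and rapamycin with Crebl2 siRNA, in this order, 34.3%, 50.7%, 58.2% and 50.7% of the genes changed by a log2 of 1 were recovered. At a log2 change of 2 the shares were 83.3%, 90.9%, 86.4% and 86.4%, and at 0.5 they were 1.49%, 4.48%, 0% and 1.49%. In the same order 83, 102, 106 and 96 genes passed, of which 4, 5, 10 and 4 had not been changed. A list shifted by a log2 of 1 in the simulation had a camera adjusted p of 3.66e-42, and 0 of 26 other lists passed. The spread in the simulation was that of the fit to all 11 arrays, those that stood apart included. The simulation drew genes independently and without a split of the arrays. It thus does not show how the tests behave with correlated genes or with such a split. The planned term for the slide was not run, since the columns used give no slide. Matching of identifiers and plots used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.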

Results

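Gene expression was measured on single-colour Illumina mouse bead arrays in mouse embryonic fibroblasts that lack p53 and TSC2. TSC2 is a brake on the growth-promoting kinase complex mTORC1, which rapamycin inhibits. Cells received an siRNA against luciferase, used as the control, or against Crebl2, a bZIP protein. They were then kept for 12 h with 20 nM rapamycin or with ethanol. The 11 arrays fell into 4 groups: 2 of luciferase siRNA with ethanol, 3 of luciferase siRNA with rapamycin, 3 of Crebl2 siRNA with ethanol and 3 of Crebl2 siRNA with rapamycin. The series title places the study in cell metabolism. The design asks what the knockdown changes, what rapamycin changes and whether the knockdown alters the response to rapamycin. The median intensity of an array lay between 98.9 and 119.3, and 46.7% to 51.0% of the probes were above background. The number of arrays limits the precision of every value given here.

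The targeted gene was measured by 1 probe close to background, detected on 9 of 11 arrays. Crebl2 had a mean log2 level of 5.48 ± 0.04 (SD, n = 2) with luciferase siRNA in ethanol and 4.83 ± 0.68 (SD, n = 3) with Crebl2 siRNA in ethanol. In rapamycin the levels were 5.53 ± 0.60 (SD, n = 3) with luciferase siRNA and 4.59 ± 0.27 (SD, n = 3) with Crebl2 siRNA. The knockdown difference was -0.65 ± 0.40 (SE; adjusted p = 0.403) in ethanol and -0.94 ± 0.36 (SE; adjusted p = 0.0735) in rapamycin, so neither passed the threshold. The mean of both differences, -0.79 ± 0.27 (SE; adjusted p = 0.0476), passed it narrowly. This call was lost in 16 of 23 alternatives. Among these were the fits without any 1 of 9 arrays, and that with the 4 arrays that stood apart from the rest as a block (adjusted p = 0.787, with 0.00941 to 0.787 over the alternatives). On replicates 1, 2 and 3 of Crebl2 siRNA with ethanol the level of Crebl2 was 5.59, 4.60 and 4.29.

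Crebrf, another bZIP gene, was above background on no array of Crebl2 siRNA with ethanol, and passed neither in ethanol (adjusted p = 0.379) nor in rapamycin, where the difference was 0.02 ± 0.19 (SE; adjusted p = 0.948). Tsc2 transcript was present in every group, at 10.17 ± 0.04 (SD, n = 2) with luciferase siRNA in ethanol. The sources used here do not give which part of the gene is missing. The p53 gene was not analysed here.

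Across all 11 arrays, 4 stood apart from the other 7: replicate 3 of Crebl2 siRNA with ethanol and the 3 arrays of Crebl2 siRNA with rapamycin. The first principal component, with 68.1% of the variance, separated these 4 arrays from the rest, and the second, with 9.89%, followed rapamycin. Correlations of log2 levels across genes lay between 0.986 and 0.991 within the 4 arrays, between 0.979 and 0.991 within the 7, and between 0.921 and 0.939 across them. Of the probes, 606 were detected (p under 0.01) on all 4 arrays and on none of the 7 (p under 0.05). The reverse held for 7 probes. The labels give no batch for any array. A fit with the 4 arrays as a block was therefore also made. Its offset is set by replicate 3 of Crebl2 siRNA with ethanol against replicates 1 and 2 alone, since only that group is split. Blocked differences for Crebl2 siRNA with rapamycin thus rest on that 1 array, and their spread comes from the other 10 arrays. Without that array, only the arrays of Crebl2 siRNA with rapamycin stand apart. Comparisons that use this group then cannot separate the siRNA or rapamycin from what set the arrays apart.

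**Figure D1:**
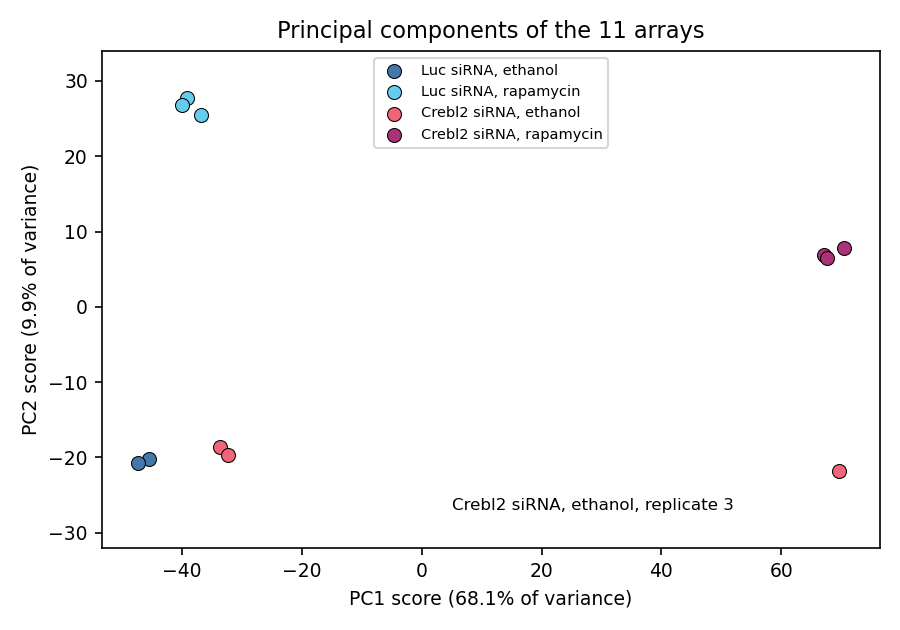
Scores of the 11 arrays on the first principal component (horizontal) and the second (vertical) of the log2 levels, 1 point per array, coloured by group. Replicate 3 of Crebl2 siRNA with ethanol lies with the 3 arrays of Crebl2 siRNA with rapamycin on the first component, which holds 68.1% of the variance.

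Rapamycin in luciferase siRNA cells lowered genes of the amino acid stress response. In the list of ATF4 targets and amino acid supply 23 of 32 measured members fell and none rose (25 fell when adjusted over the list alone), with a median log2 change of -1.02. Ddit3, which encodes the stress transcription factor CHOP, fell by 3.21 ± 0.36 (SE) on the log2 scale. The pseudokinase gene Trib3 fell by 2.88 ± 0.17 (SE), from 13.27 ± 0.11 (SD, n = 2) to 10.39 ± 0.05 (SD, n = 3). Chac1, a glutathione-degrading enzyme, changed by -2.17 ± 0.14 (SE), Mthfd2, an enzyme of mitochondrial folate metabolism, by -1.57 ± 0.17 (SE), and Ddit4, an inhibitor of mTORC1, by -2.33 ± 0.27 (SE). The list was lower than other genes by camera (adjusted p = 9.59e-24, and adjusted p = 0.0166 with an estimated correlation). Outside the list, the metabolic hormone gene Fgf21 changed by -3.37 ± 0.34 (SE; adjusted p = 0.00113) and the circadian repressor gene Ciart by -3.70 ± 0.22 (SE; adjusted p = 8.41e-05).

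Genes of glucose breakdown and biosynthesis also fell with rapamycin. In the glycolysis list 8 of 18 members fell (11 when adjusted over the list alone; camera adjusted p = 1.96e-09), among them the phosphofructokinase gene Pfkl at -1.33 ± 0.15 (SE), the glucose transporter gene Slc2a1 at -1.15 ± 0.14 (SE) and the enolase gene Eno2 at -1.44 ± 0.22 (SE). In the list of cholesterol synthesis and uptake 5 of 18 fell (10 when adjusted over the list alone; adjusted p = 1.41e-06), including the sterol synthesis enzymes Msmo1 at -1.41 ± 0.18 (SE), Hsd17b7 at -1.01 ± 0.17 (SE) and Lss at -0.77 ± 0.18 (SE). In the nucleotide synthesis list 4 of 16 fell (8 when adjusted over the list alone; adjusted p = 1.26e-05), among them Ppat of the purine pathway at -1.02 ± 0.19 (SE) and Dhodh and Umps of the pyrimidine pathway at -0.77 ± 0.16 (SE) and -0.95 ± 0.21 (SE). The hypoxia list had 3 of 13 members lower (3 when adjusted over the list alone; adjusted p = 0.000859), including Vegfa at -1.26 ± 0.19 (SE) and the collagen prolyl hydroxylase gene P4ha2 at -0.96 ± 0.19 (SE). In the fit without the block, this list did not pass for rapamycin in Crebl2 siRNA cells (camera adjusted p = 0.82; median -0.08 and mean -0.02, test upward). Nor did it pass for the mean rapamycin effect (camera adjusted p = 0.15).

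Lists tied to growth and division moved as well. In the ribosome biogenesis list 8 of 23 fell (12 when adjusted over the list alone; adjusted p = 1.3e-08), with Rrp12 at -1.43 ± 0.14 (SE), Ltv1 at -1.23 ± 0.16 (SE) and Rrp9 at -1.27 ± 0.19 (SE). In the DNA replication list 7 of 24 fell (14 fell and 1 rose when adjusted over the list alone; adjusted p = 2.67e-08), including the licensing factor gene Cdt1 at -0.77 ± 0.14 (SE), the ribonucleotide reductase gene Rrm2 at -0.94 ± 0.19 (SE) and the transcription factor gene E2f1 at -0.76 ± 0.15 (SE). The unfolded protein response list had 2 of 16 members lower (2 when adjusted over the list alone; adjusted p = 0.0193), Herpud1 at -0.63 ± 0.16 (SE) and Hyou1 at -0.59 ± 0.15 (SE). This call was lost with an estimated correlation (adjusted p = 0.0634 with an estimated correlation), and the other 9 lists that passed for this comparison kept theirs. The cyclin-dependent kinase inhibitor gene Cdkn1a changed by -2.59 ± 0.23 (SE), the lipoprotein receptor gene Lrp8 by -2.62 ± 0.22 (SE) and Stbd1, which encodes a glycogen-binding protein, by -2.41 ± 0.19 (SE).

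Fewer lists rose with rapamycin. The extracellular matrix and fibroblast list had 2 of 20 members higher (3 when adjusted over the list alone; adjusted p = 0.000229), Tagln at 1.04 ± 0.23 (SE) and Ccn2 at 0.59 ± 0.14 (SE). The list of ribosomal proteins and elongation factors had 1 of 19 higher (1 when adjusted over the list alone; adjusted p = 0.00649), Rpl22 at 0.80 ± 0.16 (SE), with a median of 0.20 over the list. Ypel1, not above background on the 2 ethanol arrays, was at least 6.90-fold higher with rapamycin (adjusted p = 0.000375). Tmem204 rose by 2.38 ± 0.19 (SE), Frat2, which encodes a binding partner of the kinase GSK3, by 2.29 ± 0.17 (SE) and the ubiquitin ligase gene Fbxo32 by 1.91 ± 0.22 (SE). Of cell types other than fibroblasts, 0 of 5 macrophage markers passed (0 when adjusted over the list alone; adjusted p = 0.916), 0 of 7 endothelial markers passed (0 when adjusted over the list alone; adjusted p = 0.423) and 1 of 5 epithelial markers was higher (1 when adjusted over the list alone; adjusted p = 0.423; median -0.03 and mean 0.16, test upward). The higher epithelial marker was Krt18, at 0.76 ± 0.17 (SE; adjusted p = 0.027).

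For rapamycin in control siRNA cells 1013 of 15835 genes passed an adjusted p of 0.05 by limma, 461 higher and 552 lower. Higher genes made up 45.5% of the calls, and 55.6% with median scaling. The count was 197 and 151 without replicate 1 or 2 of luciferase siRNA with ethanol, and 514, 513 and 432 without replicate 1, 2 or 3 of luciferase siRNA with rapamycin. It was 2001 with only the 7 arrays that lay together. Replicate 3 of Crebl2 siRNA with ethanol serves only for the spread in this comparison. Without it 12 of 18 cholesterol genes fell (against 5), 9 of 16 nucleotide synthesis genes fell and 1 rose (against 4), 5 of 13 hypoxia genes fell (against 3), 14 of 23 ribosome biogenesis genes fell (against 8), 14 of 24 DNA replication genes fell and 1 rose (against 7), 7 of 20 matrix and fibroblast genes rose (against 2) and 4 of 19 ribosomal protein genes rose (against 1).

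**Figure D2:**
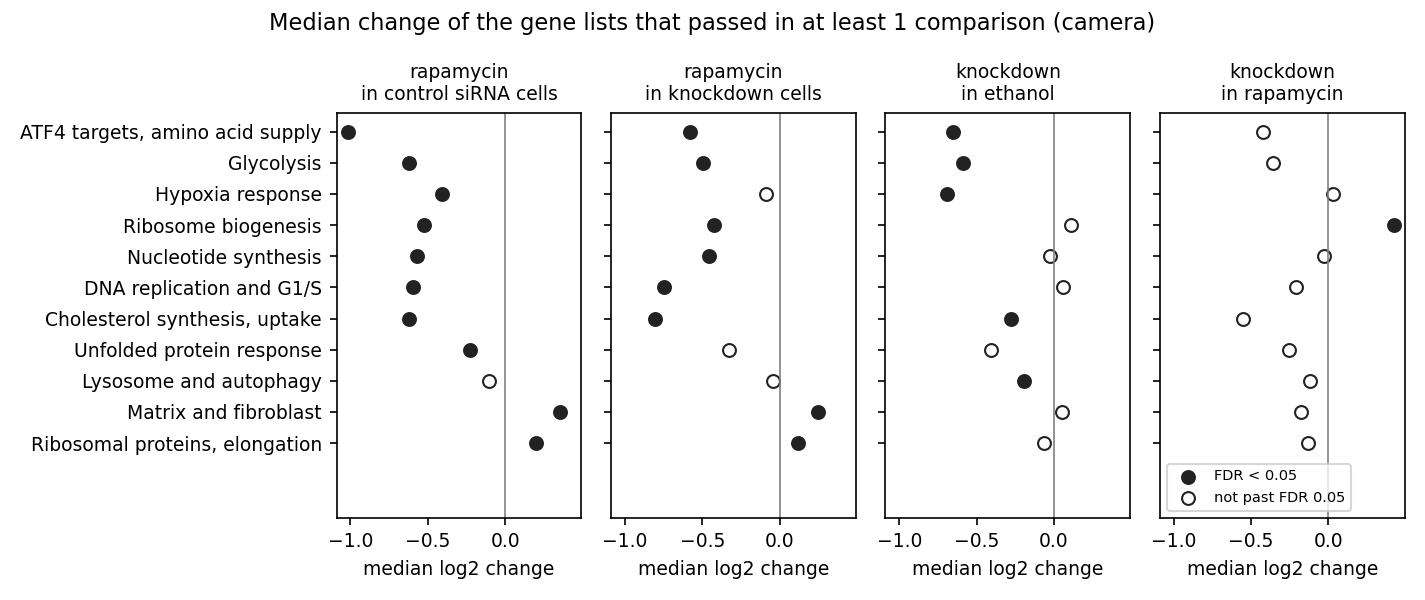
Median log2 change (horizontal) of the members of 11 gene lists (vertical) in the 4 comparisons, 1 point per list, for lists that passed camera in at least 1 of them. Filled points passed an adjusted p of 0.05 with the preset correlation, and the list of ATF4 targets lies at -1.02 for rapamycin in luciferase siRNA cells.

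The Crebl2 siRNA in ethanol was set against the same 2 control arrays. In the list of ATF4 targets 12 of 32 members fell (21 when adjusted over the list alone) with a median of -0.65, among them Ddit3 at -2.74 ± 0.36 (SE), Trib3 at -2.15 ± 0.17 (SE) and Chac1 at -1.48 ± 0.14 (SE). In the glycolysis list 7 of 18 fell (11 when adjusted over the list alone), with Pdk1, whose kinase shuts off pyruvate dehydrogenase, at -1.26 ± 0.21 (SE), Pfkl at -0.87 ± 0.15 (SE) and Slc2a1 at -0.71 ± 0.14 (SE). The hypoxia list had 2 of 13 lower (6 when adjusted over the list alone), Vegfa at -1.08 ± 0.19 (SE) and Pdk1, which is also in this list. The cholesterol list had 2 of 18 lower (2 when adjusted over the list alone), the sterol synthesis enzymes Cyp51 and Msmo1, the latter at -0.86 ± 0.18 (SE). The list of lysosome and autophagy genes had 3 of 30 lower (3 when adjusted over the list alone), among them the autophagy receptor gene Sqstm1 at -0.77 ± 0.16 (SE) and the cholesterol transporter gene Npc1 at -0.88 ± 0.18 (SE), for which 1 of 5 probes passed singly.

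By camera these 5 lists were lower than other genes, but no call held with an estimated correlation. ATF4 targets had adjusted p = 1.29e-11, and adjusted p = 0.137 with an estimated correlation. Glycolysis had adjusted p = 6.22e-07, and adjusted p = 0.137 with an estimated correlation. Hypoxia had adjusted p = 0.0131, and adjusted p = 0.137 with an estimated correlation. Cholesterol had adjusted p = 0.036, and adjusted p = 0.452 with an estimated correlation. Lysosome and autophagy had adjusted p = 0.0364, and adjusted p = 0.452 with an estimated correlation. Without replicate 3 of Crebl2 siRNA with ethanol, the array that stood apart, ATF4 targets had adjusted p = 3.3e-12, and adjusted p = 0.00394 with an estimated correlation. Glycolysis then had adjusted p = 5.62e-07, and adjusted p = 0.0207 with an estimated correlation. Hypoxia, cholesterol and lysosome and autophagy still failed with an estimated correlation, at adjusted p = 0.0502, 0.172 and 0.196, and 5 of 13 hypoxia genes fell. Of cell types other than fibroblasts, 0 of 5 macrophage markers passed (0 when adjusted over the list alone; adjusted p = 0.437), 1 of 7 endothelial markers was lower (1 when adjusted over the list alone; adjusted p = 0.72) and 0 of 5 epithelial markers passed (1 when adjusted over the list alone; adjusted p = 0.147).

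Single genes moved in both directions with the siRNA in ethanol. Fgf21 changed by -2.99 ± 0.34 (SE; adjusted p = 0.0046), the stress-induced gene Gadd45a by -2.09 ± 0.17 (SE; adjusted p = 0.000845), Ciart by -2.07 ± 0.22 (SE) and Avil, which encodes an actin-binding protein, by -2.04 ± 0.18 (SE). The growth factor gene Fgf18 rose by 2.03 ± 0.17 (SE), from 5.33 ± 0.15 (SD, n = 2) to 7.36 ± 0.03 (SD, n = 3). The transcription factor gene Sox18, not above background on the 2 control arrays, was at least 4.70-fold higher (adjusted p = 0.00766). The metallothionein gene Mt2 changed by 2.54 ± 0.51 (SE; adjusted p = 0.0264), and Id2, which encodes a repressor of bHLH factors, by 1.88 ± 0.43 (SE; adjusted p = 0.0409), though neither of its 2 probes passed when every probe was tested. For the knockdown in ethanol 635 genes passed, 158 higher and 477 lower. The count was 1064 without the array that stood apart, 457 higher and 607 lower, and with array weights it was 1663, 680 higher and 983 lower, so the excess of lower genes was smaller there. With only the compared groups in the limma fit 0 genes passed, and 1888 had an unadjusted p under 0.05, so no gene kept its call. The count was 31 and 10 without replicate 1 or 2 of the control arrays.

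The knockdown and rapamycin comparisons against these control arrays shared 72 higher genes, where independent lists would share 4.60, and 163 lower genes, where independent lists would share 16.6. The correlation of their log2 changes across genes, which are not independent replicates, was 0.415. In 100 simulations of unchanged groups against 2 shared control arrays it was 0.601. The numbers of arrays alone set that value, so comparing it with 0.415 decides nothing. The covariance was 0.0888, against 0.0531 in the simulations. The simulated covariance depends on the spread assumed for the control arrays, so it does not size their part in the overlap. The 2 control arrays were too few to split, so the part of the overlap that comes from them is not known.

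In rapamycin, 4 of the 8 largest decreases with Crebl2 siRNA held with the 4 arrays as a block. Alox5ap, which takes part in leukotriene synthesis, was at 8.01 ± 0.11 (SD, n = 3) with luciferase siRNA and 5.50 ± 0.22 (SD, n = 3) with Crebl2 siRNA, a difference of -2.51 ± 0.16 (SE; adjusted p = 6.53e-05). Ttc39a differed by -2.25 ± 0.12 (SE), Plekha6 by -2.20 ± 0.14 (SE) and the aldehyde oxidase gene Aox3 by -2.41 ± 0.19 (SE; adjusted p = 0.000353). With the block, Alox5ap differed by -2.71 (adjusted p = 0.0118), Ttc39a by -2.10 (adjusted p = 0.0102), Plekha6 by -1.92 (adjusted p = 0.0164) and Aox3 by -1.74 (adjusted p = 0.0459). These 4 genes also changed with the siRNA in ethanol, Alox5ap by -1.89, Ttc39a by -1.79, Plekha6 by -1.13 and Aox3 by -1.05.

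The ribosome biogenesis list was higher with Crebl2 siRNA in rapamycin. Of its members, 10 of 23 were higher and none lower (10 when adjusted over the list alone), with a median of 0.42 (camera adjusted p = 0.000114, and adjusted p = 0.0488 with an estimated correlation). The nucleolin gene Ncl differed by 1.20 ± 0.21 (SE), Rrp9 by 0.96 ± 0.17 (SE) and Rrn3, which encodes an initiation factor of RNA polymerase I, by 1.68 ± 0.30 (SE). Without replicate 3 of Crebl2 siRNA with ethanol, which serves only for the spread here, it had 12 members higher and adjusted p = 0.000545, and adjusted p = 0.629 with an estimated correlation. With the 4 arrays as a block the list had a median of 0.29 and adjusted p = 0.00823, and adjusted p = 0.481 with an estimated correlation, but 0 members passed, and Ncl, Rrp9 and Rrn3 had adjusted p = 0.428, 0.0832 and 0.478. No other list passed. ATF4 targets had 13 of 32 members lower and 2 higher (14 and 2 when adjusted over the list alone; adjusted p = 0.19). Of cell types other than fibroblasts, 2 of 5 macrophage markers were lower (2 when adjusted over the list alone; adjusted p = 0.524), 2 of 7 endothelial markers were lower (2 when adjusted over the list alone; adjusted p = 0.524) and 2 of 5 epithelial markers were lower (2 when adjusted over the list alone; adjusted p = 0.524).

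None of the 8 largest increases in this comparison held with that block. Since the probe with the highest mean over all arrays stood for its gene, probes high on the arrays that stood apart were favoured. Tpt1 was at 5.35 ± 0.61 (SD, n = 3) with luciferase siRNA and 12.05 ± 0.12 (SD, n = 3) with Crebl2 siRNA in rapamycin, and Rad21, a cohesin subunit, differed by 6.14 ± 1.29 (SE). The RNA helicase gene Ddx39a, not above background with luciferase siRNA, was at least 83.8-fold higher. With the block the differences were 0.09 for Tpt1 (adjusted p = 0.97), 0.07 for Rad21 (adjusted p = 0.972) and 0.40 for Ddx39a (adjusted p = 0.799). The probe of Tsc2 with the highest signal differed by -0.66 ± 0.17 (SE; adjusted p = 0.0165), while the mean of its 3 probes differed by 0.09, since 1 of the 3 probes moved the other way. For the knockdown in rapamycin 4789 genes passed, 1775 higher and 3014 lower, with a median of -0.17 over all genes. The count was 7 with the block, 3178 and 3191 without replicate 1 or 3 of luciferase siRNA with rapamycin, and 3124 without replicate 3 of Crebl2 siRNA with rapamycin.

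Rapamycin in Crebl2 siRNA cells lowered genes of DNA synthesis. In the DNA replication list 19 of 24 members fell (19 when adjusted over the list alone), with a median of -0.74 (camera adjusted p = 9.18e-10, and adjusted p = 0.0405 with an estimated correlation). Rrm2 changed by -1.56 ± 0.17 (SE), the thymidine kinase gene Tk1 by -1.17 ± 0.13 (SE) and the flap endonuclease gene Fen1 by -1.20 ± 0.14 (SE). Without replicate 3 of Crebl2 siRNA with ethanol the list had adjusted p = 0.000596, and adjusted p = 0.186 with an estimated correlation. With the 4 arrays as a block it had adjusted p = 2.4e-18, and adjusted p = 0.00811 with an estimated correlation.

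Single genes outside this list fell too. Ddit4 fell by 2.34 ± 0.24 (SE), Trib3 fell by 1.95 ± 0.15 (SE) and Ddit3 changed by -1.89 ± 0.32 (SE; adjusted p = 0.00983). Igfbp5, which encodes an insulin-like growth factor binding protein, changed by -1.96 ± 0.18 (SE), the DNA helicase gene Recql4 by -2.01 ± 0.23 (SE), the Notch target Hey1 by -1.83 ± 0.18 (SE) and the cell-cycle transcription factor gene Mybl2 by -1.83 ± 0.15 (SE). With the 4 arrays as a block Ddit3 changed by -0.99 (adjusted p = 0.0531), and the other 6 genes passed. For Recql4, 1 of 3 probes passed singly.

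Further lists fell by camera in these cells as well, though none of their calls held with an estimated correlation in the fit without the block. ATF4 targets had 18 of 32 members lower (22 lower and 2 higher when adjusted over the list alone; adjusted p = 5.64e-10, and adjusted p = 0.0886 with an estimated correlation), among them the serine hydroxymethyltransferase gene Shmt2 at -1.74 ± 0.18 (SE). The cholesterol list had 10 of 18 lower (12 when adjusted over the list alone; adjusted p = 1.4e-05, and adjusted p = 0.0886 with an estimated correlation), with Stard4 at -1.05 ± 0.12 (SE), Sc5d at -1.08 ± 0.15 (SE) and Lss at -1.11 ± 0.16 (SE). Glycolysis had 7 of 18 lower (10 when adjusted over the list alone; adjusted p = 0.000424, and adjusted p = 0.175 with an estimated correlation), with Pfkl at -1.20 ± 0.13 (SE) and the lactate dehydrogenase gene Ldha at -0.93 ± 0.13 (SE). Ribosome biogenesis had 6 of 23 lower (9 when adjusted over the list alone; adjusted p = 0.0173, and adjusted p = 0.0886 with an estimated correlation), with Rrp12 at -0.93 ± 0.12 (SE) and Nop56 at -1.39 ± 0.20 (SE). Nucleotide synthesis had 4 of 16 lower (6 lower and 1 higher when adjusted over the list alone; adjusted p = 0.0176, and adjusted p = 0.123 with an estimated correlation), with Pfas at -0.75 ± 0.12 (SE) and Dhodh at -0.79 ± 0.15 (SE). Of the genes just named Sc5d, Lss, Nop56 and Dhodh lost their call with the block, at adjusted p = 0.0542, 0.0565, 0.0565 and 0.0861.

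The matrix and fibroblast list had 2 of 20 members higher (3 when adjusted over the list alone; adjusted p = 0.00209, and adjusted p = 0.0826 with an estimated correlation), the genes of the secreted matrix proteins Ccn1 and Ccn2, the latter at 0.89 ± 0.13 (SE). The list of ribosomal proteins and elongation factors had 3 of 19 higher (3 when adjusted over the list alone; adjusted p = 0.0173, and adjusted p = 0.0886 with an estimated correlation), among them Eef1b2 at 0.70 ± 0.15 (SE) and Rpl22 at 0.60 ± 0.15 (SE). With the block Ccn1 and Eef1b2 had adjusted p = 0.172 and 0.215. Of cell types other than fibroblasts, 0 of 5 macrophage markers passed (0 when adjusted over the list alone; adjusted p = 0.593), 0 of 7 endothelial markers passed (0 when adjusted over the list alone; adjusted p = 0.82; median -0.07 and mean -0.01, test upward) and 1 of 5 epithelial markers was higher (1 when adjusted over the list alone; adjusted p = 0.562; median -0.00428 and mean 0.05, test upward).

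Without replicate 3 of Crebl2 siRNA with ethanol, rapamycin in these cells cannot be separated from the arrays that stood apart. The 8 lists depended on how those arrays were handled. With the block each of them passed, and with an estimated correlation they had adjusted p = 0.00391 for ATF4 targets, 0.00811 for DNA replication, 0.00811 for cholesterol, 0.0455 for glycolysis, 0.046 for ribosome biogenesis, 0.048 for matrix and fibroblast genes and 0.046 for ribosomal proteins, all passing, and 0.0821 for nucleotide synthesis. Without replicate 3 of Crebl2 siRNA with ethanol the calls of ribosome biogenesis (adjusted p = 0.653), nucleotide synthesis (0.152) and ribosomal proteins (0.152) were lost, and of the 8 lists only ATF4 targets passed with an estimated correlation (adjusted p = 0.0384). With the block 6 of 32 ATF4 target genes fell (against 18), 9 of 24 DNA replication genes fell (against 19), 1 of 18 cholesterol genes fell (against 10), 2 of 18 glycolysis genes fell (against 7), 2 of 23 ribosome biogenesis genes fell (against 6) and 1 of 16 nucleotide synthesis genes fell (against 4). When that replicate was left out 11 of 18 glycolysis genes fell (against 7), 10 of 23 ribosome biogenesis genes fell and 3 rose (against 6), 9 of 16 nucleotide synthesis genes fell and 2 rose (against 4), 6 of 19 ribosomal protein genes rose and 1 fell (against 3) and 7 of 20 matrix and fibroblast genes rose and 3 fell (against 2). In the blocked fit ribosome biogenesis, nucleotide synthesis and ribosomal proteins had adjusted p = 5.36e-08, 0.0077 and 0.00174.

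The largest increases in Crebl2 siRNA cells were those of the chromatin protein gene Hmga2 at 3.31 ± 0.84 (SE), the sterol exporter gene Abca1 at 3.25 ± 0.78 (SE) and the cyclin gene Ccng2 at 2.88 ± 0.72 (SE). Under the block these changes were 0.66 (adjusted p = 0.133), 0.78 (adjusted p = 0.0484) and 0.63 (adjusted p = 0.195). For rapamycin in knockdown cells 1391 genes passed, 404 higher and 987 lower. Higher genes made up 29% of the calls, against 14.6% with median scaling, 46.5% in the authors' normalized values and 47.7% with the 4 arrays as a block. With only the compared groups in the limma fit 0 genes passed, and 3436 had an unadjusted p under 0.05, so no gene kept its call. The count was 222 with the 4 arrays as a block. With rapamycin and the arrays that stood apart no longer separable, it was 6145 without replicate 3 of Crebl2 siRNA with ethanol. It was 270 and 262 without replicate 1 or 2 of that group, and 387, 445 and 362 without replicate 1, 2 or 3 of Crebl2 siRNA with rapamycin.

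**Figure D3:**
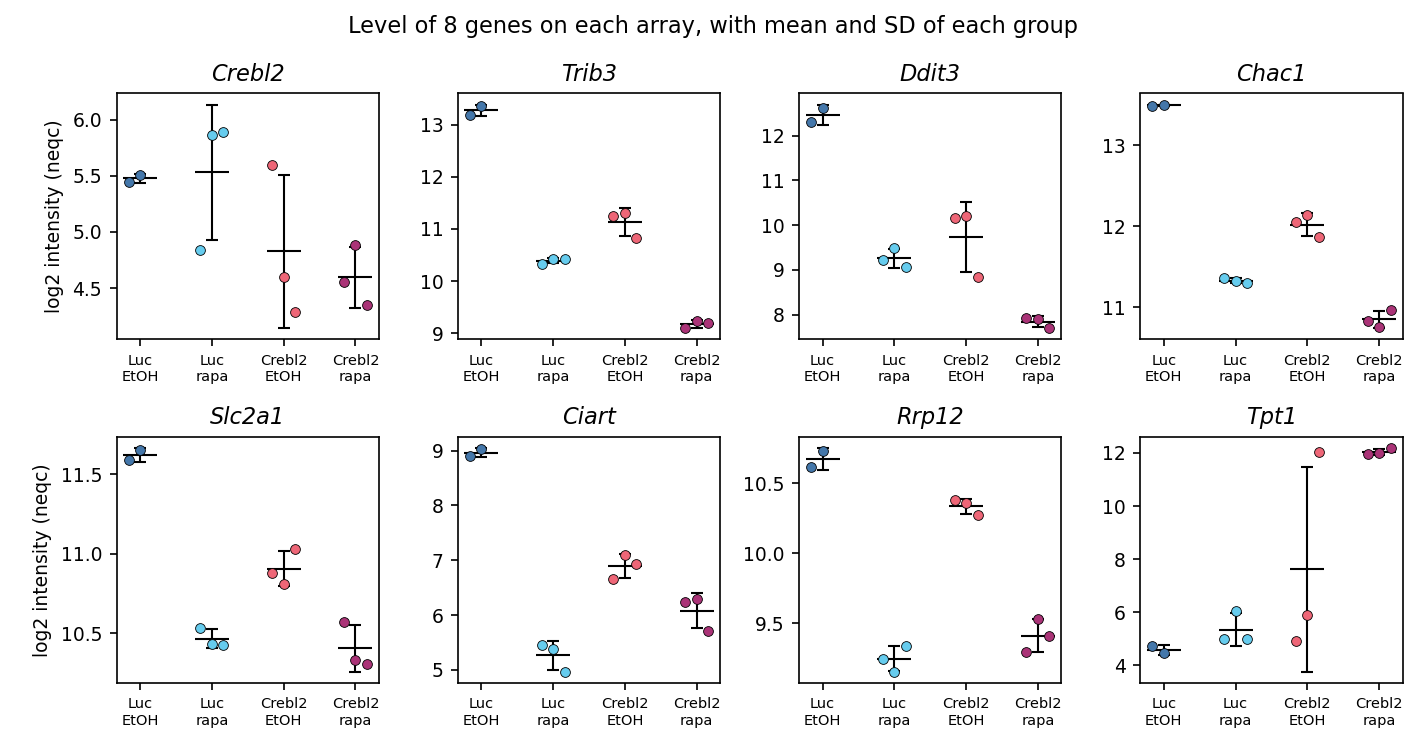
Log2 intensity (vertical) of 8 genes on each of the 11 arrays by group (horizontal), 1 point per array, with bars for the mean and SD of each group. Trib3 has its highest mean, 13.27, with luciferase siRNA in ethanol, and for Tpt1 replicate 3 of Crebl2 siRNA with ethanol, at 12.02, lies with the Crebl2 siRNA arrays in rapamycin.

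The test of whether the knockdown altered the response to rapamycin passed for 5 genes. Ciart had log2 differences with rapamycin of -3.70 in luciferase siRNA cells and -0.81 in Crebl2 siRNA cells, a difference of 2.88 ± 0.30 (SE; adjusted p = 0.0311). Trem3, a receptor gene of myeloid cells, and the G protein subunit gene Gng8 passed with adjusted p = 0.0345 and 0.0345. Ttc22 passed with adjusted p = 0.0345, and Derl3, which takes part in protein quality control of the endoplasmic reticulum, with adjusted p = 0.0351. These 4 genes were each above background on no array of at least 1 group, so the size of their difference was not measured. The count was 8 with the 4 arrays as a block, where Ttc22 had adjusted p = 0.07. By limma it was 3643 without replicate 3 of Crebl2 siRNA with ethanol, 2 without replicate 2 of that group, 1 without replicate 3 of Crebl2 siRNA with rapamycin, and 0 without any 1 of the other 8 arrays, where 1425 to 1844 genes had an unadjusted p under 0.05. The fit with 3643 genes cannot separate the interaction from the arrays that stood apart. With all 11 arrays 2157 genes had an unadjusted p under 0.05. Of the 5 genes 3 had a positive difference, or 60%, against 100% of 2 genes with median scaling and 44.3% of 61 genes in the authors' normalized values.

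Across all 15835 genes, which are not independent replicates, the rapamycin responses with each siRNA correlated with r = 0.303 (Spearman rho 0.335). Their calls shared 109 higher and 283 lower genes, where independent lists would share 11.8 and 34.4. For the mean rapamycin effect 2353 genes passed, 855 higher and 1498 lower. Higher genes made up 36.3% of them, 47% in the authors' normalized values and 48.8% with the 4 arrays as a block. Over these genes the median change in the direction of the mean effect was 0.634 with luciferase siRNA and 0.599 with Crebl2 siRNA. Without replicate 3 of Crebl2 siRNA with ethanol these medians were 0.357 and 0.743, and 5865 genes passed. The count was 1189 and 1196 without replicate 1 or 2 of luciferase siRNA with ethanol.

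The knockdown effects in ethanol and in rapamycin correlated across genes with r = 0.71 (Spearman rho 0.555), and with r = 0.243 without replicate 3 of Crebl2 siRNA with ethanol. Their calls shared 86 higher and 340 lower genes, where independent lists would share 17.7 and 90.8. Both comparisons set arrays that stood apart against arrays that did not, which can add shared calls. With the 4 arrays as a block 7 genes passed for the knockdown in rapamycin. For the mean knockdown effect 4873 genes passed, 1823 higher and 3050 lower, and 418 with the 4 arrays as a block. The count was 2919 and 2731 without replicate 1 or 2 of luciferase siRNA with ethanol.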

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

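The tests on the 4 arrays that stood apart, the values with them as a block or without replicate 3 of Crebl2 siRNA with ethanol, and the tests of the list of ATF4 targets were chosen only after the results were seen, while the counts of other splits were planned.

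The response to rapamycin differed between the siRNAs, by the test of the difference itself, for 5 genes. The difference on the log2 scale was 2.88 for the circadian repressor gene Ciart (adjusted p 0.000225 to 0.266 over the alternatives). The other 4 genes were above background on no array of at least 1 group, so their fitted values are not measured sizes. These were 1.79 for Trem3 (adjusted p 0.000415 to 0.266), 1.70 for Gng8 (8.86e-05 to 0.336), -2.42 for Ttc22 (0.000669 to 0.336) and -1.74 for Derl3 (0.00051 to 0.336). The highest adjusted p of each was without replicate 2 of luciferase siRNA with ethanol, and the lowest without replicate 3 of Crebl2 siRNA with ethanol.

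The same test passed for 5 lists, in each of which the responses lay higher with Crebl2 siRNA. ATF4 targets and amino acid supply had a median difference of 0.33 (3 of 32 members higher when adjusted over the list alone; adjusted p = 6.16e-06, and adjusted p = 0.318 with an estimated correlation). The hypoxia list had a median difference of 0.42 (2 of 13 members higher when adjusted over the list alone; adjusted p = 0.00241, and adjusted p = 0.0899 with an estimated correlation), and ribosome biogenesis had a median difference of 0.19 (0 of 23 members higher when adjusted over the list alone; adjusted p = 0.00294, and adjusted p = 0.0899 with an estimated correlation). Lysosome and autophagy had a median difference of 0.14 (0 of 30 members higher when adjusted over the list alone; adjusted p = 0.0368, and adjusted p = 0.624 with an estimated correlation), and glycolysis had a median difference of 0.17 (0 of 18 members higher when adjusted over the list alone; adjusted p = 0.0368, and adjusted p = 0.624 with an estimated correlation). By limma 0 members of these lists passed over all genes, where 2157 genes had an unadjusted p under 0.05.

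The lists for the interaction depended on the arrays that stood apart. The fit without replicate 3 of Crebl2 siRNA with ethanol cannot separate the interaction from those arrays. With the 4 arrays as a block ATF4 targets had a median of 0.54 and held with an estimated correlation (adjusted p = 0.00653). Hypoxia, lysosome and glycolysis passed there (adjusted p = 0.0141, 0.00401 and 0.00242) but not with an estimated correlation (adjusted p = 0.128 for each). Ribosome biogenesis was lost (adjusted p = 0.0844), and DNA replication passed downward (adjusted p = 0.0141, and adjusted p = 0.369 with an estimated correlation). Without replicate 3 of Crebl2 siRNA with ethanol ATF4 targets, hypoxia and ribosome biogenesis passed (adjusted p = 0.0123, 0.0285 and 0.0123), none of them with an estimated correlation (adjusted p = 0.241, 0.277 and 0.706), while lysosome and glycolysis were lost (adjusted p = 0.571 and 0.601).

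The first pattern weighed was that 4 arrays stood apart. If a change in the cells had caused this, 2 probes of 1 gene would move together. Between replicate 3 of Crebl2 siRNA with ethanol and replicates 1 and 2, the changes of 2 probes correlated with r = 0.128 over 5141 genes, against 0.522 for the response to rapamycin with luciferase siRNA. Where both probes were detected on every array the values were 0.134 and 0.757 over 2079 genes. Of 453 genes with a probe higher by over 2 on that array, 237 had another probe that changed by under 0.5. These genes were chosen for an extreme probe and no comparison rate was taken, so this count decides nothing. By the same measure 1 gene had a probe lower by over 2. The correlations point to a technical difference between the 4 arrays and the other 7, such as an array or labelling batch, for which the labels give none. They cannot say which of these sets departs, or at which step. Of the probes, 606 were detected on all 4 and on none of the 7, and 7 the other way, so signal missing on the 7 arrays stayed open.

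A wrong label on replicate 3 of Crebl2 siRNA with ethanol was argued against. Over the 1013 genes called for rapamycin with luciferase siRNA, the 3 Crebl2 siRNA arrays in rapamycin differed from this array by a median of 0.44 in the direction of that response (SD 0.00266 between the 3 arrays), which a rapamycin-treated culture would not show. A stronger knockdown in the 4 cultures was argued against as the whole cause. For replicates 1 and 2 of Crebl2 siRNA with ethanol against luciferase siRNA, 2 probes of 1 gene correlated with r = 0.342. The lower end of its 95% bootstrap interval was 0.312, while on the 4 arrays the highest r was 0.152 (upper end 0.186). The bootstrap drew genes, so it holds no spread between arrays. The first r rests on means of 2 arrays and each of the others on 1 array, which by itself can lower r. A smaller part from the knockdown stayed open, since the Crebl2 probe lies too close to background to rank the arrays, at 4.29 on replicate 3, 4.60 on replicate 2 and 5.59 on replicate 1 of that group.

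The second pattern was the lower list of ATF4 targets with Crebl2 siRNA in ethanol. The 4 arrays that stood apart were argued against as its cause, since without replicate 3 of Crebl2 siRNA with ethanol the list had a median of -0.46 (adjusted p = 3.3e-12, and adjusted p = 0.00394 with an estimated correlation). A high level in the 2 control arrays alone stayed open. In rapamycin, where other control arrays serve, the list had adjusted p = 0.473 and a median of -0.06 with the 4 arrays as a block, but a list that misses the threshold there does not show that the knockdown had no effect. An effect of the siRNA on these genes that depends on active mTORC1 stayed open too. The interaction of this list tests that dependence, but a high level in the 2 control arrays would move it the same way, so it does not separate these explanations. Whether the siRNA acted through loss of Crebl2 was not tested. On replicate 1 of Crebl2 siRNA with ethanol Crebl2 lay at 5.59, against 5.45 and 5.50 on the control arrays. Trib3 was at 11.25 there, and at 11.31 on replicate 2, where Crebl2 was 4.60. The Crebl2 probe lies close to background, so these levels decide nothing.

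Counts of calls were set against other splits of the arrays. For the knockdown in rapamycin the real split gave 4789 genes and the highest of the others 0, with 1 of 10 splits as large, and for rapamycin in Crebl2 siRNA cells the values were 1391 and 0, with 1 of 10. In both cases the splits are too few for a share under 0.05. For the mean rapamycin effect 1 of 100 splits, the real one, gave as many as 2353 genes and the highest of the others 7. A random split of these arrays thus rarely gives such a count. For the mean knockdown effect 3 of 100 splits gave as many as the real 4873, and the highest of the others was 5009. That share is under 0.05, but the other splits as large had 5009 and 4965 genes. They set replicate 1 or 2 of Crebl2 siRNA with ethanol beside the luciferase siRNA arrays and kept replicate 3 with the Crebl2 siRNA arrays in rapamycin. These splits follow the 4 arrays that stood apart, so the count does not separate the siRNA from what set those arrays apart. With the 4 arrays as a block 418 genes passed.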

How the results depend on the processing

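The 4 arrays as a block or left out, and the count of genes with at least 2 kept probes that agree, were chosen only after the results were seen, and the other alternatives were planned. The 130 values of named genes were set against 2513 alternatives, of which 2143 stayed on the same side of the threshold, 364 kept the direction but lost the call, 5 gained a call and 1 turned the direction of a call. Among those on the same side, 17 changed sign, in 7 values of Crebl2, Crebrf and Tsc2 that passed in neither fit. The call that turned was Tsc2 in knockdown in rapamycin, 0.0895 with the mean of kept probes, since 1 of its 3 probes moved the other way. For other values that moved, the cause was not tested. Signal limits what can be seen, as at most 51.0% of probes on an array were above background.

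Counts of genes moved with the processing. Without background correction the knockdown in ethanol had 1054 genes (from 635), rapamycin in control siRNA cells 1627 (from 1013), rapamycin in knockdown cells 2125 (from 1391) and the interaction 64 (from 5). In the authors' normalized values, and in the series matrix, which holds the same values, these were 1176 for the knockdown in ethanol, 1606 for rapamycin in control siRNA cells and 61 for the interaction. The interaction also had 20 genes with no filter, 17 with a strict filter, 35 with normexp and offset 50, 2 with median scaling, 8 with the mean of kept probes, 1 with every named probe tested and 72 with a trended, robust fit. Counting only genes with at least 2 kept probes that agree left 32 for the knockdown in ethanol, 416 for the knockdown in rapamycin (from 4789), 52 and 80 for rapamycin in control siRNA cells and in knockdown cells, 0 for the interaction, 439 for the mean knockdown effect (from 4873) and 193 for the mean rapamycin effect (from 2353), by construction fewer genes. Of the genes called, those changed at least 1.5-fold were 3041 for the mean knockdown effect and 1329 for the mean rapamycin effect.

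The fit mattered as well. With only the compared groups in the limma fit 0 genes passed for the knockdown in ethanol (1888 at unadjusted p under 0.05) and 0 for rapamycin in knockdown cells (3436), while 6106 passed for the knockdown in rapamycin and 1400 for rapamycin in control siRNA cells. Array weights gave replicate 3 of Crebl2 siRNA with ethanol 0.106 and the other arrays 0.948 to 1.67. This nearly leaves that replicate out, so Crebl2 siRNA with rapamycin is hard to separate from the arrays that stood apart. The weighted counts were 1663 for the knockdown in ethanol, 2598 for rapamycin in control siRNA cells and 6705 for rapamycin in knockdown cells. For the interaction and the mean rapamycin effect they were 3793 and 6145. With the 4 arrays as a block the counts were 1064, 7, 2483 and 222 for the knockdown in ethanol, the knockdown in rapamycin, rapamycin in control siRNA cells and rapamycin in knockdown cells, 8 for the interaction and 418 for the mean knockdown effect. Without the 4 arrays rapamycin in control siRNA cells had 2001.

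Arrays of different groups share only a replicate number, and the labels do not say what it means. Of 15 same-numbered pairs, 0 correlated over 0.1 in their deviations from group means. Their median r was -0.00119, against 0.00209 for other pairs. Of 11 arrays, 5 correlated best with their own number, but no comparison rate was taken, so this count decides nothing. With the replicate number as a block the limma counts were 200 for the knockdown in ethanol, 584 for rapamycin in control siRNA cells and 0 for the interaction (2703 at unadjusted p under 0.05). The correlation of the rapamycin responses was then 0.115 (from 0.303), and 3 lists passed for the interaction. A block for the slide was not run.

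Leaving out 1 array of the groups compared at a time gave 10 to 1064 genes for the knockdown in ethanol, 3124 to 3388 for the knockdown in rapamycin, 151 to 514 for rapamycin in control siRNA cells, 262 to 6145 for rapamycin in knockdown cells, 0 to 3643 for the interaction (1425 at unadjusted p under 0.05 by limma at the lowest), 2731 to 5325 for the mean knockdown effect and 1189 to 5865 for the mean rapamycin effect. Where replicate 3 of Crebl2 siRNA with ethanol was among those left out, the count was highest without it. Without this replicate, Crebl2 siRNA with rapamycin cannot be separated from the arrays that stood apart. The replicate is in neither group of the knockdown in rapamycin or of rapamycin in control siRNA cells, so their ranges do not cover its removal. Where 1 array of luciferase siRNA with ethanol was left, it is assumed to vary like the other groups, and the counts were 31 and 10 for the knockdown in ethanol, 197 and 151 for rapamycin in control siRNA cells. The lists that passed numbered 2 to 6 for the knockdown in ethanol, 1 for the knockdown in rapamycin, 9 to 11 for rapamycin in control siRNA cells, 5 to 8 for rapamycin in knockdown cells, 3 to 6 for the interaction, 3 to 4 for the mean knockdown effect and 8 to 10 for the mean rapamycin effect.

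The size of the rapamycin response with luciferase siRNA was 0.634, 0.357 to 0.83 with 1 array left out and 1.17 over the 200 genes with the smallest p. With Crebl2 siRNA it was 0.599, 0.594 to 0.743 with 1 array left out, 0.398 without background correction, 0.451 with normexp and offset 50, 0.389 in the authors' normalized values, 0.722 over genes at adjusted p under 0.01 and 0.985 over the 200 genes. The correlation of the rapamycin responses was 0.231 to 0.354 with 1 array left out and 0.407 with the 4 arrays as a block, and the correlation of the knockdown effects was 0.243 to 0.801 with 1 array left out.

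Numbers of lists moved with the test. With an estimated correlation 0 passed for the knockdown in ethanol (from 5), 1 for rapamycin in knockdown cells (from 8), 0 for the interaction (from 5) and 0 for the mean knockdown effect (from 3). Fry, which does not compare with other genes, passed 10, 18, 16 and 14 lists for the knockdown in ethanol, the knockdown in rapamycin, rapamycin in control siRNA cells and rapamycin in knockdown cells, and 19 and 17 for the mean knockdown and mean rapamycin effects. With no filter 4 passed for the knockdown in rapamycin and 5 for the mean knockdown effect, with a strict filter 3 for the knockdown in ethanol, with median scaling 2 for the interaction and with the 4 arrays as a block 6 for the mean knockdown effect. Over the changes of filter, scaling and probes, 0 of 336 list calls turned the direction of the test, 10 were lost and 1 changed the sign of the median, the lysosome list for the interaction with median scaling (-0.01, adjusted p = 0.517).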

Other observations

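The lists described first were picked only after their values were seen, and no test was added for them. Other regulators of the fibroblasts moved as single genes with Crebl2 siRNA in ethanol, though their lists did not pass. CREB targets had 1 higher and 4 lower of 18 members (1 and 5 when adjusted over the list alone; camera adjusted p = 0.165), with the early growth response gene Egr1 at -1.15 ± 0.13 (SE; adjusted p = 0.00467) and Gadd45b at 1.16 ± 0.17 (SE; adjusted p = 0.0085). Insulin feedback and FoxO genes had 0 higher and 2 lower of 19 members (1 and 3 when adjusted over the list alone; camera adjusted p = 0.954), with Txnip, which encodes an inhibitor of glucose uptake, at -1.73 ± 0.21 (SE; adjusted p = 0.00512) and the repressor gene Bcl6 at -0.99 ± 0.13 (SE; adjusted p = 0.00514). Circadian clock genes had 0 higher and 2 lower of 12 members (0 and 2 when adjusted over the list alone; camera adjusted p = 0.251), with Dbp at -1.06 ± 0.17 (SE; adjusted p = 0.0124) and Clock at -0.77 ± 0.17 (SE; adjusted p = 0.0339). With rapamycin in luciferase siRNA cells, CREB targets had 1 higher and 2 lower of 18 members (1 and 3 when adjusted over the list alone; camera adjusted p = 0.257), with Atf3 at -1.78 ± 0.27 (SE; adjusted p = 0.00478) and Gadd45b at 0.89 ± 0.17 (SE; adjusted p = 0.0155). Insulin feedback and FoxO genes had 3 higher and 1 lower of 19 members (5 and 1 when adjusted over the list alone; camera adjusted p = 0.235) in those cells, with the receptor gene Igf1r at 0.84 ± 0.17 (SE; adjusted p = 0.0203).

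Over both siRNAs the mean rapamycin effect was downward for the lists of mitosis and of the unfolded protein response. With single siRNAs mitosis did not pass (camera adjusted p = 0.0561 with luciferase siRNA and 0.164 with Crebl2 siRNA). The unfolded protein response passed with luciferase siRNA (camera adjusted p = 0.0193) but not with Crebl2 siRNA (0.193). For the mean rapamycin effect mitosis genes had 1 higher and 6 lower of 17 members (1 and 7 when adjusted over the list alone; camera adjusted p = 0.0429), and adjusted p = 0.181 with an estimated correlation. Cdk1 was at -0.65 ± 0.10 (SE) and Aurka at -0.70 ± 0.11 (SE). The unfolded protein response list had 0 higher and 4 lower of 16 members (1 and 10 when adjusted over the list alone; camera adjusted p = 0.0231), and adjusted p = 0.0732 with an estimated correlation. Its member Sdf2l1 was at -1.05 ± 0.22 (SE). Of the 10 lists that passed for the mean rapamycin effect, the other 8 kept their call with an estimated correlation. With the 4 arrays as a block mitosis and the unfolded protein response had adjusted p = 0.00487 and 0.00121, and adjusted p = 0.0725 and 0.0721 with an estimated correlation. Both were lost without replicate 3 of Crebl2 siRNA with ethanol (adjusted p = 0.234 and 0.229), and with an estimated correlation so were ribosome biogenesis (adjusted p = 0.259) and nucleotide synthesis, DNA replication and ribosomal proteins (adjusted p = 0.0677 for each).

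Over both treatments the knockdown effects were as follows. ATF4 targets had 1 higher and 21 lower of 32 members (2 and 24 when adjusted over the list alone; camera adjusted p = 5.07e-05), and adjusted p = 0.476 with an estimated correlation. Glycolysis had 0 higher and 11 lower of 18 members (0 and 14 when adjusted over the list alone; camera adjusted p = 0.000615), and adjusted p = 0.476 with an estimated correlation. Ribosome biogenesis had 12 higher and 0 lower of 23 members (13 and 0 when adjusted over the list alone; camera adjusted p = 0.000615), and adjusted p = 0.0972 with an estimated correlation. In the blocked fit 4 members of ATF4 targets were lower, 1 of glycolysis was lower and by limma 0 of ribosome biogenesis passed. These lists still passed there, at adjusted p = 4.06e-06, 0.000308 and 0.0122, and had adjusted p = 0.0258, 0.0737 and 0.381 with an estimated correlation. With replicate 3 of Crebl2 siRNA with ethanol left out, the values with an estimated correlation were 0.0454, 0.104 and 0.285. Over all 189 tests of lists, 42 passed, and 51 had a median, mean and test of unlike sign, 0 of them among those that passed.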
